A study of Homo sapiens with 6 samples.

How the data were processed

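The data are bulk RNA-seq counts from 6 libraries of organoids made from WTC-11, an established human induced pluripotent stem cell line. The organoids are called induced secretory ameloblast organoids in the labels, ameloblasts being the epithelial cells that lay down tooth enamel. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase and made into stranded, paired-end 100 bp mRNA libraries. Per the submitters' processing notes, FastQC 0.11.9, HISAT2 2.2.1, featureCounts, Subread 2.0.1 and DESeq2 1.34.0 were used with the build GRCh38, without the role or order of each being stated. The deposited table holds raw counts per gene symbol, 1 column per library, as made by the authors. The gene annotation release, the strand setting and the treatment of reads that fit several genes are not given in the sources used here.

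Several features of the counts bear on how they can be read. In every library more genes had 2 counts than 1 (1594 against 1050 in untreated replicate 1), a pattern that arises when both mates of a pair are counted singly, so that the counts may exceed the number of sequenced fragments. Between the libraries of a group, the variance over genes with 10 to 10000 summed counts was 2.28 to 3.87 times the counting noise. This noise takes each count as a separate fragment, so part of the ratio may come from mates counted singly. Where reads of near-identical genes, such as the pregnancy-specific glycoprotein (PSG) family on chromosome 19, cannot be told apart, the counting could drop or share them, and the levels of single members are uncertain. The same holds for overlapping genes and for antisense partners. Intervals and limits for 0 counts cover counting error only, and they take each count as a separate fragment. If mates were counted singly, the intervals are too narrow and the lower bounds on folds too high.

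Columns were assigned to samples by the library names in the labels, and groups were taken from the sample titles. Of 41129 symbols, 9643 had no count in any library. After edgeR's filterByExpr, 21755 genes with 99.98% of all counts were tested. Libraries were scaled by TMM factors, and CPM values (counts over the scaled library total, times 1e6) were computed from the deposited counts with these factors. Means are given with the SD over n = 2 libraries. A group of 2 libraries with 0 counts allows up to 3 counts over the group, or 0.0178, 0.0192 and 0.0155 CPM in untreated wild type, C3-DLL4 wild type and C3-DLL4 knockout. Folds against such a group are lower bounds computed from that limit. Where the lower group held 1 to 3 counts, the ratio is given with its exact 95% counting interval.

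Differences were tested with edgeR 4.0.16 (quasi-likelihood fit and test, all 6 libraries, no covariates, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 3 residual degrees of freedom, 16.5 prior degrees of freedom and a biological coefficient of variation of 3.2%. Log2 fold changes of single genes are given with a standard error (SE) from the quasi-likelihood fit. An SE given with the median of a set of genes comes from the spread across those genes, taken as independent. It does not measure the spread between libraries. The 3 comparisons were C3-DLL4 against untreated in wild type, knockout against wild type with C3-DLL4 in both, and knockout with C3-DLL4 against untreated wild type. The first pair of comparisons shares the C3-DLL4 wild-type libraries. To show what sharing gives where libraries vary but group means do not, unchanged groups were simulated in 20 draws. The overlap was also counted with 1 of the shared libraries in each comparison. The pipeline was also tested on simulated data with 200 changed genes. In the agonist comparison it recovered 70.77%, 76.92% and 85.71% of genes changed 1.5-fold, 2-fold and 4-fold, with 2 unchanged genes called among 20979 genes run. In the knockout comparison these shares were 53.23%, 86.36% and 93.75%, with 9 unchanged genes called among 20980. Only these 200 genes were changed, in both directions, whereas 80.6% and 80% of tested genes were called in the data. The simulation therefore does not test the scaling where most genes differ.

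For 30 gene lists, camera (limma 3.58.1) was run on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each list was also tested with an estimated correlation and with fry. The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. By that rule, the text names DLX3 and the 10 genes with the highest and the 10 with the lowest log2 fold change in the agonist and knockout comparisons, and 5 of each in the third. These had an adjusted p under 0.05, a mean of at least 2 CPM in 1 of the groups, no overlap between the groups' libraries, and a symbol that is not a clone, antisense or pseudogene name. With 2 libraries against 2, chance alone parts the groups fully in 33.3% of genes. Up to 4 members per list were named by smallest adjusted p, and any member of the Notch target, secretory-stage and maturation-stage lists. For the overlap, the 10 genes per direction with the largest smaller change were taken.

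The alternatives were RLE, library totals and upper quartile scaling, both a looser and a stricter count filter, DESeq2 1.42.0, limma-voom, fits on the 4 libraries compared, the replicate number as a block, stricter thresholds and leaving out each library. Halved counts, counts without mitochondrial genes and FN1, and the split of the shared libraries were added after seeing the data. Gene positions come from GENCODE 29 on GRCh38, which matched 36166 symbols (87.9%).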

Results

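Gene expression was measured by RNA-seq in 6 libraries of WTC-11 induced secretory ameloblast organoids, in 3 groups of 2. Wild-type organoids were left untreated or received C3-DLL4, a soluble designed trimeric scaffold carrying the Notch ligand DLL4, at 50 nM for 24 h from day 24 of differentiation. DLX3 knockout organoids received the same treatment. DLX3 is a homeobox transcription factor of teeth, hair, skin and placenta. Total counts were 77443586 and 82333827 in untreated wild type, 96403727 and 95860105 in C3-DLL4 wild type, and 88422553 and 77348174 in C3-DLL4 knockout. The labels call the libraries of a group biological replicates without saying whether they came from separately started cultures, so p-values measure only the spread between these libraries. Within groups, Spearman correlations were 0.9949 to 0.9967 across genes, which are not independent replicates. On the first principal component (72.3% of the variance) the C3-DLL4 wild-type libraries stood apart from the other 4, and the second (24%) parted untreated wild type from knockout.

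DLX3, the targeted gene (chromosome 17, 49990005 to 49995224 in GRCh38, minus strand), was at 7.86 ± 0.2 CPM in untreated wild type, 23.1 ± 0.3 CPM in C3-DLL4 wild type and 1.51 ± 0.44 CPM in C3-DLL4 knockout (SD, n = 2 each). It rose 2.94-fold with C3-DLL4 (log2 fold change 1.56 ± 0.10 SE) and was 15.4-fold lower in the knockout than in wild type with the same treatment (log2 fold change -3.95 ± 0.13). Against untreated wild type the knockout was 5.25-fold lower (log2 fold change -2.39 ± 0.13). The knockout libraries still held 289 DLX3 counts, and which part of the gene was altered is not given in the sources used here. Several epithelial genes that were not targeted fell further than DLX3 in the knockout, among them SP6, TP63 and COL17A1, so the DLX3 level is a limited check of the labels.

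**Figure D1:**
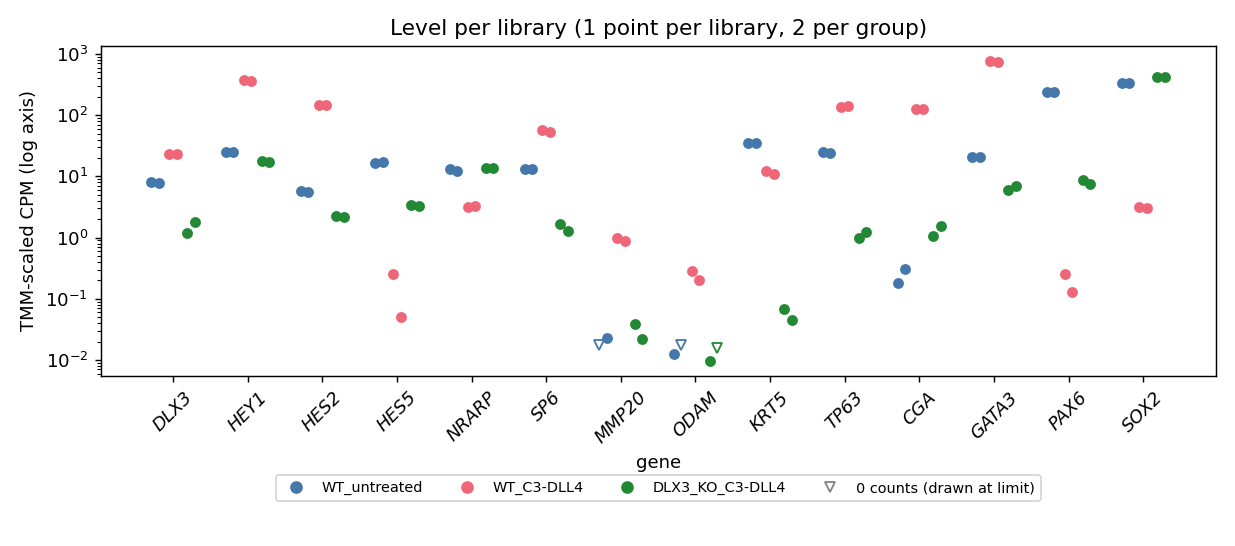
TMM-scaled CPM (log axis) of 14 genes in each of the 6 libraries, 1 point per library and 1 colour per group; open triangles mark libraries with 0 counts, drawn at the limit that 3 counts over the group allow. DLX3 lies near 23.1 CPM in C3-DLL4 wild type and near 1.51 CPM in the knockout, HEY1 is highest and HES5 lowest in C3-DLL4 wild type.

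The first comparison set wild-type organoids given C3-DLL4 for 24 h against untreated ones. Rose and fell mean higher and lower than in the untreated libraries, since a difference between cultures apart from treatment was not excluded. With the agonist, the lists of basal epithelium, simple epithelium, trophoblast and interferon-response genes rose and those of neural and cell cycle genes fell (camera), though none of these calls held with an estimated correlation (adjusted p = 0.085 to 0.14). FN1, encoding the matrix protein fibronectin, rose from 253 ± 2.5 to 62400 ± 230 CPM (SD, n = 2), the basal epithelial genes COL17A1 from 107 ± 2.1 to 3940 ± 1.7 CPM and LAMB3 from 0.917 ± 0.022 to 976 ± 14 CPM, and the simple-epithelial keratin KRT7 from 62.5 ± 0.99 to 2850 ± 6.5 CPM. PAX6, a neural and eye transcription factor, fell 1240-fold from 241 ± 2.8 CPM and CRABP1, a retinoic acid binding protein, 679-fold from 457 ± 26 CPM. Of 21755 genes tested, 8585 were higher and 8947 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 5110 and 5488 of them by at least 2-fold.

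The genes listed beforehand as Notch targets went both ways. Of the 15 listed, 5 rose and 10 fell (median log2 fold change -1.51). HEY1 rose 14.9-fold (25 ± 0.38 to 372 ± 5.4 CPM), HES2 26-fold (5.68 ± 0.14 to 148 ± 1.5 CPM), MYC 5.62-fold and the receptor NOTCH3 1.83-fold. HES5 fell 110-fold (17 ± 0.59 to 0.153 ± 0.14 CPM), LFNG 187-fold, HEYL 28.4-fold, DTX1 14-fold and NRARP 3.97-fold. HES1 fell by 0.18 on the log2 scale (SE 0.04), and HES4, at 27.2 ± 2.1 and 32.2 ± 0.61 CPM, rose by 0.24 with TMM scaling but was lower with library totals (-0.13). As a set the list was not called (camera adjusted p = 0.49, and 0.61 with an estimated correlation), and fry gave the opposite direction (up, adjusted p = 0.00044). The receptors, ligands and modifiers of the pathway were not called either (camera adjusted p = 0.63), with 9 higher and 11 lower of 21. The ligands DLL1 and JAG1 fell 38.4-fold and 4.89-fold, and DTX3L rose 32.1-fold.

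Secretory-stage enamel genes rose together in 6 of 7 tested members (median log2 fold change 2.03, camera adjusted p = 0.036, adjusted p = 0.21 with an estimated correlation). FAM83H rose 6.54-fold (48.1 ± 0.89 to 315 ± 10 CPM), FAM20C, a kinase of secreted proteins, 7.56-fold, the transcription factor SP6 4.09-fold and TUFT1 3.93-fold, while ACP4 was lower (log2 fold change -0.84 ± 0.35). The enamel protease MMP20 stayed below 1 CPM (0.0116 ± 0.016 to 0.922 ± 0.07 CPM, a ratio of 77.5 with a counting interval of 21.1 to 646). The main enamel matrix genes AMELX, AMBN and ENAM had at most 5 counts in any library, where library totals were 77348174 to 96403727 counts. They thus had almost no counts in any of the 3 groups and were below the count filter, so their change was not tested. The 7 tested members do not include them, and the call of the list says nothing about these matrix genes. Of 25 maturation-stage genes tested, 13 rose and 11 fell (camera adjusted p = 0.61, and 0.64 with an estimated correlation). ITGB6, an integrin, rose 93.9-fold (9.15 ± 0.49 to 858 ± 2.3 CPM), the chloride channel CFTR 9.52-fold, ODAPH 20.8-fold and the bicarbonate exchanger SLC4A2 2.52-fold. ALPL, tissue-nonspecific alkaline phosphatase, fell 91.5-fold from 99.1 ± 1.2 CPM, and WDR72, SLC24A4, CA2 and SLC13A5 also fell. KLK4 (0.0231 ± 0.033 to 0.166 ± 4e-04 CPM) and ODAM (0.00613 ± 0.0087 to 0.243 ± 0.054 CPM) were near the detection limit, and AMTN had no counts. Leaving out untreated replicate 1 ended the calls of KLK4 (edgeR adjusted p = 0.25) and ACP4 (0.058), as did C3-DLL4 replicate 1 (0.076 and 0.13), C3-DLL4 replicate 2 for KLK4 (0.076) and untreated replicate 2 for ACP4 (0.094), and DESeq2 called neither (0.12 for both).

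Markers of cell types were among the lists with the largest medians. All 15 trophoblast markers rose (median log2 fold change 5.43, camera adjusted p = 4.6e-06), GATA3 36.2-fold to 759 ± 17 CPM, VTCN1 33.7-fold to 402 ± 3.8 CPM, IGFBP3 27.1-fold to 6320 ± 18 CPM and XAGE2 595-fold to 273 ± 3.3 CPM; several, such as GATA3 and IGFBP3, are also made by other epithelia. Simple epithelium markers rose in 16 of 17 members (7.4e-07 by camera), KRT8 13.5-fold to 6890 ± 37 CPM and KRT18 19.6-fold. Basal epithelium markers rose in 16 of 20 and fell in 3 (camera adjusted p = 0.00018), with ITGB4 12.6-fold higher. Those that fell were the keratins KRT5 and KRT15, and PKP1. KRT5 was at 35 and 35.5 CPM in the untreated libraries and 12.4 and 11.1 CPM with C3-DLL4, and KRT15 at 27.2 and 29.1, then 15 and 16.4 CPM. The keratin KRT14 stayed below 1 CPM in these libraries, while the keratin KRT17 rose. All 18 neural and neural crest markers fell (median -7.57, or -7.49 with a gene at 0 counts set to its bound, camera adjusted p = 2.1e-06), MAP2 24.9-fold and NEFM 264-fold. With an estimated correlation the adjusted p was 0.085 for the trophoblast and neural lists and 0.14 for both epithelial lists. Mitochondrial genes took 2.61% to 2.71% of counts in untreated and 2.48% to 2.49% in C3-DLL4 libraries, ribosomal protein genes 6.49% to 6.53% and 3.67% to 3.69%, and FN1 5.05% to 5.09% of counts with C3-DLL4.

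All 16 interferon-response genes rose (median log2 fold change 7.22, or 6.50 at the bound; camera adjusted p = 1.8e-06, adjusted p = 0.085 with an estimated correlation). MX1, an antiviral GTPase, rose 389-fold to 502 ± 9.7 CPM, IFI6 93.8-fold, OAS3 76.5-fold and IFIT3 631-fold. Lysosome and endocytosis genes rose in 27 of 28 members (camera adjusted p = 3.5e-08), the proteases CTSL 14.3-fold and CTSD 7.86-fold, and vacuolar ATPase subunits rose in 14 of 19 (0.0048 by camera), ATP6V0E1 5.86-fold. The p53 targets CDKN1A and MDM2 rose 11.3-fold and 4.56-fold in a list where 13 of 15 rose (camera adjusted p = 0.0013). Their adjusted p with an estimated correlation was 0.085, 0.14 and 0.19. Cell cycle genes fell in 24 of 25 members (camera adjusted p = 3.4e-07, adjusted p = 0.085 with an estimated correlation), TOP2A 6.33-fold and PLK1 6.02-fold. Wnt feedback targets fell in 10 of 12 (camera adjusted p = 0.004), AXIN2 34.4-fold and SP5 193-fold, and all 9 hedgehog targets fell (0.00035 by camera), PTCH1 20.8-fold, with adjusted p = 0.14 and 0.19 with an estimated correlation. Immediate early genes rose in 9 of 14, FOS 10-fold (camera adjusted p = 0.046, 0.25 with an estimated correlation). That call ended without untreated replicate 1 (0.066) or C3-DLL4 replicate 2 (0.057).

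The other lists were not called by camera, with adjusted p from 0.25 to 0.91. Higher and lower members numbered 4 and 1 of 5 calcium-binding phosphoproteins, 11 and 11 of 25 dental transcription factors, 17 and 12 of 32 calcium transport genes, 13 and 10 of 28 pH regulation genes, 8 and 3 of 11 mineralisation markers and 6 and 8 of 17 epidermal differentiation genes. They numbered 8 and 13 of 21 mesenchyme, 3 and 4 of 8 pluripotency and 5 and 3 of 10 endothelial markers, and 8 and 10 of 18 endoplasmic reticulum stress, 5 and 10 of 16 hypoxia, 8 and 6 of 14 BMP, 5 and 5 of 11 FGF and 9 and 8 of 17 sterol genes. Median and mean differed in sign for calcium transport (0.17 and -0.07), dental transcription factors (0.04 and -0.12) and epidermal differentiation (0.11 and -0.71), and camera and fry gave opposite directions for the phosphoprotein, dental transcription factor and mesenchyme lists. Counts adjusted over the list alone were the same in each list of the agonist and knockout comparisons.

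Single genes were ranked by fitted log2 fold change, which puts genes at or near 0 counts in 1 group first. Of the 10 that ranked highest, PSG6 and C5orf46 were at least 1240-fold and 553-fold higher, the long noncoding RNA UCA1 at least 947-fold, KLRC1 at least 638-fold, APOL3 at least 292-fold, APBB1IP at least 255-fold and FPR1 at least 209-fold. OAS2 rose 2740-fold to 167 ± 3.7 CPM, PSG4 had a ratio of 4310 (counting interval 1190 to 35600) and APOL1 of 3090 (1060 to 15000). Among the 10 that ranked lowest were homeobox genes of the HOX clusters, which pattern the hindbrain and trunk. HOXB8 was at least 698-fold lower, HOXA5 at least 187-fold and HOXA9 at least 183-fold, and HOXB9 fell from 81.8 ± 2.4 CPM by a ratio of 6390 (counting interval 1770 to 52800). The neuropeptide SST fell 4830-fold from 131 ± 1.7 CPM, the neural genes NEUROG1, ADCYAP1, EN2 and SCRT2 were at least 418-fold, 340-fold, 184-fold and 146-fold lower, and THCAT155, which had no position in the annotation, at least 179-fold. All 20 had an adjusted p of at most 5e-12 (edgeR quasi-likelihood test, Benjamini-Hochberg). Scaling set the balance of calls: with library totals alone, 6611 genes were higher and 11315 lower (36.9% against 49% higher), and the median of all genes moved by -0.37 on the log2 scale.

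The second comparison asked how C3-DLL4-treated organoids differed without DLX3. The lists of basal, simple and epidermal epithelium, trophoblast and interferon-response genes fell in the knockout, and those of neural and hedgehog genes rose (camera), though none of these calls held with an estimated correlation (adjusted p = 0.1 to 0.24). COL17A1 fell 121-fold (3940 ± 1.7 to 32.5 ± 0.16 CPM, SD, n = 2), KRT7 192-fold (2850 ± 6.5 to 14.8 ± 0.41 CPM) and FN1 88.4-fold. The transcription factor SIX6 rose 875-fold to 197 ± 3.9 CPM and GAD2, a GABA-synthesising enzyme, 1260-fold to 58.4 ± 0.65 CPM. In all, 8887 genes were higher and 8519 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 5670 and 4515 of them by at least 2-fold.

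Basal epithelium markers fell in all 20 members (median log2 fold change -5.40, camera adjusted p = 1e-08), DSP 40.1-fold and ITGB4 158-fold. Simple epithelium markers fell in 16 of 17 (4.1e-08 by camera), KRT8 31.6-fold and KRT18 49.9-fold, and epidermal differentiation genes in 14 of 17 (0.0016 by camera), IVL 167-fold. All 15 trophoblast markers fell (median -6.60, or -5.96 at the bound, camera adjusted p = 3.3e-06), GATA3 118-fold and VTCN1 61-fold. With an estimated correlation the adjusted p was 0.1 for the basal, simple epithelium and trophoblast lists and 0.14 for the epidermal list. Neural markers rose in 16 of 18 (median 6.05, camera adjusted p = 5.1e-05, adjusted p = 0.1 with an estimated correlation), ELAVL3 353-fold and STMN2 340-fold. Mitochondrial genes took 0.236% to 0.244% of counts in the knockout, where C3-DLL4 wild type had 2.48% to 2.49%, and ribosomal protein genes 4.61% to 4.73%.

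All 16 interferon-response genes fell (camera adjusted p = 2.8e-06, adjusted p = 0.1 with an estimated correlation), MX1 452-fold to 1.11 ± 0.053 CPM. Lysosome genes fell in 26 of 28 (camera adjusted p = 9.3e-08), CTSL 18.1-fold, vacuolar ATPase subunits in 15 of 19 (0.0019 by camera), ATP6V1E1 4-fold, and sterol synthesis genes in 15 of 17 (0.00032 by camera). With an estimated correlation the adjusted p was 0.1, 0.13 and 0.1. The p53 targets fell in 13 of 15 (0.00077 by camera), GDF15 29.5-fold, and immediate early genes in 11 of 14 (0.013 by camera), FOS 23.7-fold, with adjusted p = 0.18 and 0.19 with an estimated correlation. Hedgehog targets rose in 8 of 9 (camera adjusted p = 0.0032, adjusted p = 0.24 with an estimated correlation), PTCH1 46.2-fold, and the ligand SHH 66.7-fold.

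Among Notch targets 9 rose and 5 fell (camera adjusted p = 0.64). HEY1 fell 21.4-fold to 17.4 ± 0.52 CPM, HES2 66.3-fold and MYC 20.9-fold, while HES5 rose 21.6-fold to 3.35 ± 0.051 CPM, LFNG 55.4-fold, DTX1 53.3-fold, NRARP 4.29-fold and HES1 2.54-fold. HEY2, at 0.481 ± 0.3 and 0.627 ± 0.26 CPM, was not called: its log2 fold change was 1.23 without C3-DLL4 replicate 2 (edgeR adjusted p = 0.013) and -0.14 without replicate 1, and HES7 lost its call without replicate 2 (0.098). Secretory-stage genes fell in 5 of 7 (median -1.90, camera adjusted p = 0.097), SP6 37.2-fold to 1.46 ± 0.24 CPM and FAM83H, TUFT1 and FAM20A each by 3.72-fold or 3.74-fold, while ACP4 rose 2.46-fold and FAM20C was at 30.8 ± 0.12 and 31.4 ± 1.7 CPM (called higher with library totals, log2 fold change 0.55). Of 25 maturation-stage genes 8 rose and 12 fell (camera adjusted p = 0.47), ITGB6 51.8-fold lower, CFTR 39.4-fold lower, WDR72 7.82-fold lower, ALPL 41.3-fold higher and the calcium buffer CALB1 90.6-fold higher. None of the Notch, secretory or maturation lists was called with an estimated correlation (adjusted p = 0.7, 0.27 and 0.53).

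The other 15 lists were not called by camera, with adjusted p from 0.074 to 0.92. Higher and lower members numbered 13 and 7 of 21 Notch receptors and modifiers, 1 and 3 of 5 phosphoproteins, 9 and 10 of 25 dental transcription factors, 17 and 14 of 32 calcium transport, 12 and 12 of 28 pH regulation and 4 and 6 of 11 mineralisation genes. They numbered 11 and 9 of 21 mesenchyme, 4 and 3 of 8 pluripotency, 4 and 4 of 10 endothelial, 8 and 17 of 25 cell cycle, 10 and 6 of 18 endoplasmic reticulum stress, 9 and 7 of 16 hypoxia, 9 and 2 of 12 Wnt, 7 and 7 of 14 BMP and 8 and 3 of 11 FGF genes. Median and mean differed in sign for pH regulation (-0.13 and 0.30), BMP targets (0.22 and -0.28) and endothelial markers (-0.01 and 0.45), and camera and fry gave opposite directions for Notch targets, phosphoproteins, dental transcription factors, calcium transport and mesenchyme. Without C3-DLL4 replicate 2 the Wnt list was called (up, camera adjusted p = 0.043).

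By the same rank, the genes with the largest falls were the cytidine deaminase CDA, at least 1480-fold lower, PADI1, at least 1040-fold, CSF2RB, at least 715-fold, the riboflavin transporter SLC52A3, at least 509-fold, LCN2, at least 417-fold, S100A7, at least 385-fold, and PKHD1, at least 353-fold. PSG2 fell 4180-fold from 92.4 ± 0.21 CPM, OAS2 3150-fold, and PSG9 by a ratio of 3840 (counting interval 1060 to 31700). Besides SIX6 and GAD2, the largest rises were of ACKR1, at least 357-fold, THCAT155, at least 355-fold, the homeobox gene NKX2-2, at least 349-fold, TMEM271, at least 313-fold, ADGRA1, at least 156-fold, the neuronal chromatin gene ACTL6B, at least 154-fold, and HAPSTR2, at least 128-fold, while RAB3C had a ratio of 1150 (counting interval 207 to 45600). All 20 had an adjusted p of at most 4.3e-12 (edgeR quasi-likelihood test, Benjamini-Hochberg). With library totals alone, 12456 genes were higher and 5446 lower (69.6% against 51.1% higher), and the median of all genes moved by 0.53 on the log2 scale.

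**Figure D2:**
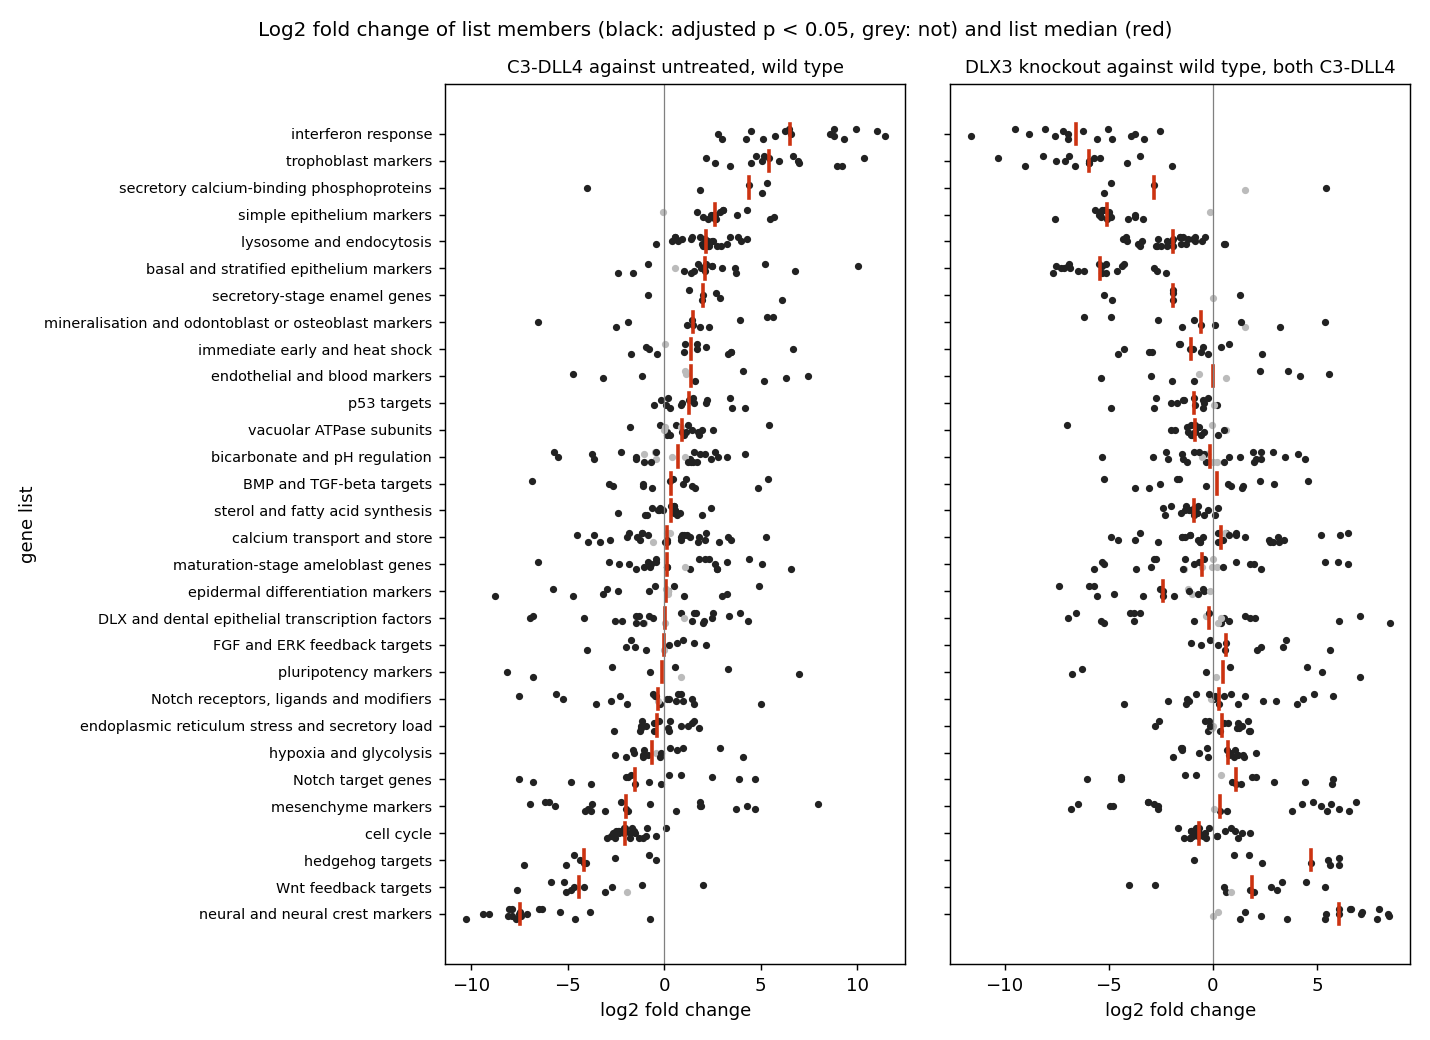
Log2 fold change (x axis) of the members of 30 gene lists (y axis) with C3-DLL4 (left) and in the knockout (right), 1 point per gene, black where the adjusted p was under 0.05 and grey otherwise; red bars are list medians, and genes with a group at 0 counts are drawn at their bound. Interferon, trophoblast and epithelial lists lie to the right on the left panel (interferon median 6.50) and to the left on the right panel (trophoblast median -5.96), and the neural list goes from -7.49 to 6.05.

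The third comparison set the treated knockout against untreated wild type, which differ in both genotype and treatment. The imprinted long noncoding RNA MEG3 (chromosome 14, 100779410 to 100861031) was 837-fold higher in the knockout, 1600 ± 6.9 against 1.91 ± 0.21 CPM (SD, n = 2; 30.2 ± 0.54 CPM in C3-DLL4 wild type), its neighbour MEG9 had a ratio of 1740 (counting interval 480 to 14300), GAD2 was 741-fold higher, and MMP7 and WT1 were at least 149-fold and 135-fold higher. The keratin KRT1 was at least 4550-fold lower, from 70.4 ± 0.82 CPM, and HOXB3, VIT, HOXC6 and HOXB4 were at least 1580-fold, 570-fold, 558-fold and 299-fold lower. These 10 genes had an adjusted p of at most 2.2e-11 (edgeR quasi-likelihood test, Benjamini-Hochberg). In all 8351 genes were higher and 8055 lower, 3837 and 3248 of them by at least 2-fold. Basal epithelium markers fell in 18 of 20 (camera adjusted p = 8.9e-07), simple epithelium markers in 16 of 17 (8.9e-07) and epidermal differentiation genes in 12 of 17 (0.003), with adjusted p = 0.15, 0.19 and 0.19 with an estimated correlation. Cell cycle genes fell in 23 of 25, or 24 adjusted over the list alone (camera adjusted p = 1.1e-08, 0.15 with an estimated correlation), Wnt feedback targets in 9 of 12 (0.0035 and 0.19) and sterol genes in 15 of 17 (0.00014 and 0.15). FGF and ERK feedback targets rose in 11 of 11 (camera adjusted p = 4.8e-05, adjusted p = 0.15 with an estimated correlation). The other 23 lists were not called. Genotype and treatment cannot be parted here, since untreated knockout organoids were not analysed here.

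The changes of the first and second comparison ran in opposite directions. HSD3B1, a placental steroid enzyme, went from 0.17 ± 0.14 to 222 ± 4 CPM with C3-DLL4 in wild type and was at 0.181 ± 0.12 CPM in the knockout (SD, n = 2), and the neuronal gene STMN2 from 142 ± 2.6 to 0.263 ± 0.17 and 89.8 ± 2.6 CPM. OAS2, PSG2, PSG4, PSG5, PSG6, PSG9, NLRP2, XAGE3 and ACTBL2 followed the course of HSD3B1, and THCAT155, ACTL6B, RAB3C, STMN4, SCRT2, HAPSTR2, EN2, ADCYAP1 and TMEM271 that of STMN2. Altogether 6584 genes were higher with C3-DLL4 and lower in the knockout and 6286 the reverse (edgeR calls), where independent lists would share 3362 and 3655. Only 1002 were higher and 1150 lower in both. Across 15715 genes at a mean of 1 CPM or more the log2 fold changes correlated at r = -0.834, with a covariance of -4.53. Because both comparisons use the C3-DLL4 wild-type libraries, unchanged groups were simulated with this sharing. They gave r = -0.51 and a covariance of -0.00578, with 0 opposite calls in each of 20 draws. The draws held only the spread between libraries of a group, so the lack of opposite calls decides little. A deviation of the whole C3-DLL4 wild-type group, which enters both comparisons with opposite signs, was not simulated. Part of the excess over independent lists may come from the sharing. With 1 of the 2 shared libraries given to each comparison, a split chosen after the data were seen, opposite calls numbered 12105 or 12127 (12870 unsplit), and the covariance was -4.59 or -4.61. There the lone library is assumed to vary like the other groups, and if the 2 came from 1 culture the split does not remove the sharing.

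**Figure D3:**
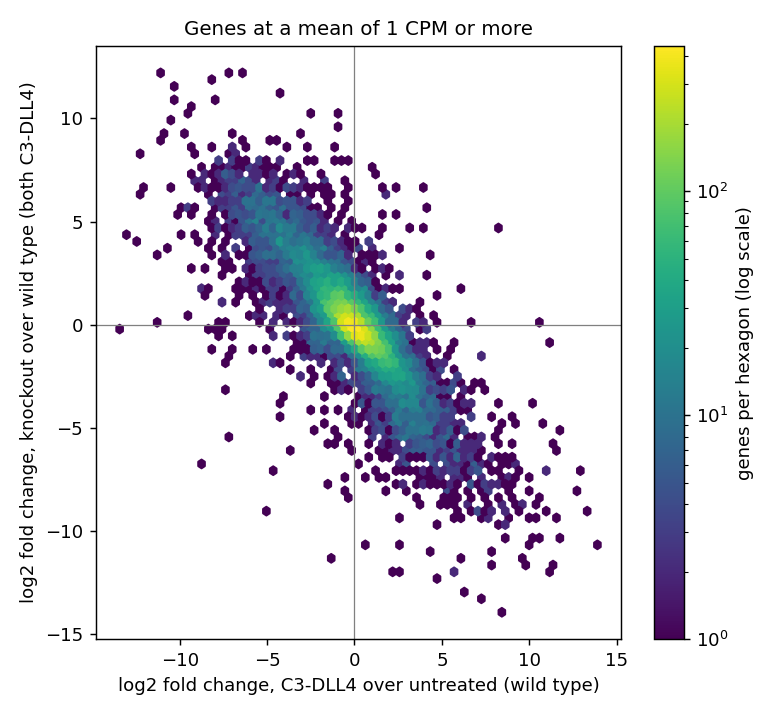
Log2 fold change of C3-DLL4 over untreated in wild type (x axis) against that of knockout over wild type with C3-DLL4 in both (y axis), for genes at a mean of 1 CPM or more, coloured by genes per hexagon on a log scale. The cloud runs from upper left to lower right (r = -0.834, against -0.51 in simulated unchanged groups that share libraries).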

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

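All alternatives were planned, except halving the counts, leaving out mitochondrial genes and FN1, and splitting the C3-DLL4 wild-type libraries between the first 2 comparisons, which were chosen after the data were seen and ended or turned none of the results they were run on. Genes passing the test numbered 8585 higher and 8947 lower with C3-DLL4, 8887 and 8519 in the knockout, and 8351 and 8055 in the third comparison, and they stayed within 1.5 times those counts in all alternatives but the following. A 2-fold minimum, by construction fewer genes, left 5110 and 5488, 5670 and 4515, 3837 and 3248, and 7166 opposite calls against 12870, and library totals left 5446 lower in the knockout against 8519. Upper quartile scaling moved the median of all genes by -0.23 and 0.26 in the first and second comparison, and the split of calls was 41.2% and 60.7% higher. Library totals turned the log2 change of 6 named values, HES4 (-0.13), ORAI1 (-0.20) and TFRC (-0.22) with C3-DLL4 and SLC26A1 (0.11), SLC26A4 (0.02) and TFRC (0.48) in the knockout, and upper quartile scaling turned ORAI1 (-0.06) and TFRC (-0.08) with C3-DLL4 and TFRC (0.22) in the knockout; by construction these scalings shift all genes by about 1 amount per comparison, which turns changes smaller than it. Calls were gained in the knockout by HEY2 (0.92), FAM20C (0.55), RELT (0.53) and CA2 (0.72) with library totals, FAM20C (0.29), RELT (0.27) and CA2 (0.45) with upper quartile scaling, TFRC (-0.06) with RLE size factors and with DESeq2, and KLK4 (-2.84) with limma-voom, while RELT was -0.01 and not called with RLE size factors and with DESeq2. Calls ended for HES4 (0.01) with upper quartile scaling, KLK4 (2.37) with library totals, and ACP4 (-0.81) and KLK4 (2.86) with DESeq2, all with C3-DLL4, and in the knockout for SLC26A1 with upper quartile scaling (-0.16) and DESeq2 (-0.44). An estimated correlation between members ended the camera calls with C3-DLL4, with adjusted p = 0.085 (lysosome, neural, trophoblast, cell cycle, interferon), 0.14 (vacuolar ATPase, basal epithelium, simple epithelium, Wnt), 0.19 (p53, hedgehog), 0.21 (secretory stage) and 0.25 (immediate early). An estimated correlation between members ended the camera calls in the knockout, with adjusted p = 0.1 (lysosome, basal epithelium, simple epithelium, neural, trophoblast, interferon, sterol), 0.13 (vacuolar ATPase), 0.14 (epidermal), 0.18 (p53), 0.19 (immediate early) and 0.24 (hedgehog). The estimated correlation was -0.037 (neural), -0.025 (trophoblast), -0.03 (cell cycle) and -0.046 (interferon), below the preset 0.01. A stronger correlation than the preset therefore did not end the calls of these lists. For some other lists it lay above the preset, such as 0.028 (lysosome) and 0.078 (simple epithelium). With an estimated correlation, 0 of the 30 lists were called in each of the 3 comparisons, so losing a call did not set a list apart. The cause was not tested further. Fry, which asks of each list alone whether its members changed, passed the threshold where camera had not with C3-DLL4, with adjusted p = 2.3e-06 (calcium transport), 3.7e-06 (pluripotency), 5e-06 (Notch receptors and modifiers), 9.6e-06 (maturation stage), 1.4e-05 (BMP), 3.1e-05 (sterol), 3.2e-05 (FGF), 5.4e-05 (mineralisation), 7.4e-05 (endoplasmic reticulum stress, hypoxia), 0.00011 (endothelial), 0.00039 (epidermal) and 0.001 (pH regulation), and gave the opposite direction with adjusted p = 3.6e-05 (dental transcription factors), 0.00044 (Notch targets), 7e-04 (phosphoproteins) and 0.078 (mesenchyme). Fry, which asks of each list alone whether its members changed, passed the threshold where camera had not in the knockout, with adjusted p = 5.3e-07 (FGF), 5.4e-06 (endoplasmic reticulum stress), 7.1e-06 (BMP), 9.7e-06 (pluripotency), 1.6e-05 (maturation stage), 1.8e-05 (Notch receptors and modifiers), 2.3e-05 (secretory stage, Wnt), 5.7e-05 (cell cycle), 0.00013 (mineralisation), 0.00038 (hypoxia) and 0.023 (pH regulation), and gave the opposite direction with adjusted p = 5.4e-06 (calcium transport), 1.6e-05 (phosphoproteins), 5.7e-05 (Notch targets), 0.0013 (dental transcription factors) and 0.0077 (mesenchyme). Fry called 29, 29 and 30 of the 30 lists in the 3 comparisons. It asks only whether members changed, and 80.6%, 80% and 75.4% of all tested genes were called there (edgeR). A fry call therefore does not set a list apart. Why its direction differed from that of camera in some lists was not tested. The filter on CPM ended the immediate early call (0.084) and turned 2 lists that were not called, dental transcription factors with C3-DLL4 (0.81) and calcium transport in the knockout (0.99); the cause was not tested. Fitting only the 4 libraries compared ended the immediate early call (0.062) and turned the endothelial list in the knockout (0.9, not called); the cause was not tested. Leaving out 1 library at a time, where an arm with 1 library is assumed to vary like the other groups, gave camera adjusted p of 0.69 to 0.96 for dental transcription factors with C3-DLL4, 0.037 to 0.066 for immediate early genes with C3-DLL4, 0.89 to 1 for pH regulation in the knockout, 0.76 to 1 for mesenchyme in the knockout, 0.86 to 1 for endothelial markers in the knockout and 0.043 to 0.099 for Wnt targets in the knockout; the immediate early call ended without untreated replicate 1 or C3-DLL4 replicate 2, the Wnt list was called without C3-DLL4 replicate 2, and the others turned without being called. Of the log2 changes in the knockout that changed sign this way, none called in the main test, the ranges were HEY2 -0.14 to 1.23, FAM20C -0.03 to 0.08, RELT -0.04 to 0.05 and SLC26A4 -0.98 to 0.18. Leaving out a library also ended calls with C3-DLL4 (ACP4 -0.97 to -0.70, KLK4 1.82 to 6.86 and ORAI1 0.13 to 0.23) and in the knockout (HES7 0.74 to 1.64 and SLC26A1 -0.50 to -0.35), and gained calls in the knockout (HEY2 -0.14 to 1.23, CA2 0.01 to 0.38, TFRC -0.08 to -0.01 and KLK4 -6.85 to -0.33). The samples share only a replicate number (correlations of same-numbered deviations 0.066, 0.065 and 0.04), and with a replicate block the counts were 8492 and 8790, 8721 and 8433, and 8198 and 7926; the block ended 1 call, the immediate early list with C3-DLL4 (0.056), of those run with it, which leave out the lists of the third comparison and the gene sets chosen after the results were seen, while of all gene calls 17246 of 17532, 17119 of 17406 and 16070 of 16406 were kept. DESeq2 gave no adjusted p for 5494, 4884 and 6105 genes, and AMELX, AMBN, ENAM and AMTN had too few counts to be tested.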

Other observations

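The gene sets described first, and the tests of exchanged labels, differing cultures, removal by 1 factor, more neural cells and a switch of imprint, were chosen after the results were seen. HOX genes fell in wild type with C3-DLL4 in 26 of 27 tested members (median log2 fold change -7.40) and were also lower in the knockout than in untreated wild type in 25 of 27 (median -8.52). HOXB9 was at 81.8 ± 2.4 CPM in untreated wild type, 0.0128 ± 0.018 CPM in C3-DLL4 wild type and 0.221 ± 0.016 CPM in the knockout (SD, n = 2 each), and HOXB1 at 20.7 ± 0.21, 0.109 ± 0.081 and 0.0111 ± 0.016 CPM. Transcription factors of the forebrain and eye field rose in the knockout against C3-DLL4 wild type in 9 of 10 members, and against untreated wild type 7 rose and 3 fell. SIX3 was at 18.5 ± 0.43, 1.38 ± 0.042 and 234 ± 1.2 CPM in the same order, and NKX2-1 at 0.374 ± 0.026, 2 ± 0.031 and 200 ± 3.3 CPM. OTX2 was at 274 ± 1.1, 5.39 ± 0.41 and 161 ± 4.7 CPM.

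Pregnancy-specific glycoprotein genes rose with C3-DLL4 in all 10 tested members and fell in the knockout in all 10, and none was called between knockout and untreated wild type (edgeR). PSG5 was at 0.28 ± 0.24, 326 ± 2.4 and 0.193 ± 0.04 CPM in untreated wild type, C3-DLL4 wild type and knockout (SD, n = 2 each), PSG2 at 0.0354 ± 0.015, 92.4 ± 0.21 and 0.0207 ± 0.0019 CPM, and PSG1 at 0.0769 ± 0.022, 17.1 ± 1.1 and 0.0705 ± 0.072 CPM.

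The neural and trophoblast marker lists set C3-DLL4 wild type apart from the other 2 groups, while between knockout and untreated wild type camera called neither (adjusted p = 0.13 and 0.52) and fry both (2.7e-05 and 0.00012). Fry called all 30 lists in that last comparison, so its calls do not mark out these 2. Gene length and GC content are argued against as the whole cause, since their trends took 0.84% of the variance and lay at most 1.69 from their median for any gene, and after a loess correction the neural median with C3-DLL4 was -7.54 (SE 0.23) and the trophoblast median 5.31 (SE 0.73), against -7.57 and 5.43 before. Whether the untreated and knockout labels were exchanged could not be decided from these lists. C3-DLL4 wild type stood apart from the libraries labelled knockout as well, with medians of -6.05 (SE 0.64) for the neural and 6.60 (SE 0.57) for the trophoblast list. Since an exchange would leave the pattern in place, these lists cannot tell whether one occurred. DLX3 was lower under the knockout label (1.51 ± 0.44 against 7.86 ± 0.2 CPM in untreated wild type), a limited check. Cultures of different cell makeup apart from treatment and genotype might also give the pattern: the 2 libraries of a group differed by at most 0.10 in the median log2 CPM of the list that is highest there, but if a group was grown as 1 culture its libraries share that makeup. Effects of C3-DLL4 and of the genotype, which the design names, stay among the open explanations and were not tested apart from the culture, which would take separately started cultures and untreated knockout organoids.

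All 13 mitochondrial mRNAs were lower in the knockout, by a median of -4.19 against C3-DLL4 wild type and -3.39 against untreated wild type, MT-CO1 at 248 ± 1.4 against 5450 ± 63 and 4490 ± 80 CPM. The 75 nuclear genes of the respiratory chain tested were also lower, but by much less, with medians of -0.41 (SE 0.06) and -0.44 (SE 0.03). A joint fall of like size is thus argued against, while a smaller fall of the nuclear genes is not. Enrichment of nuclear RNA stays open, with medians of 0.74 (SE 1.06) and 0.07 (SE 0.80) over 7 nuclear-retained RNAs that went both ways. Removal of mitochondrial reads by 1 factor also stays open, because the changes against untreated wild type had an SD of 0.49 (-4.18 to -2.47), and a difference between the organoids on top of such a factor could give that spread. A lower mitochondrial RNA content in this knockout is an untested biological explanation.

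MEG3, MEG8 and MEG9 were high in the knockout, at 1600 ± 6.9, 28.9 ± 0.53 and 20.7 ± 0.59 CPM, against 30.2 ± 0.54, 0.397 ± 0.053 and 0.186 ± 0.1 CPM in C3-DLL4 wild type and 1.91 ± 0.21, 0.107 ± 0.0046 and 0.0116 ± 0.016 CPM in untreated wild type, so they also rose with C3-DLL4 (log2 fold change 3.98, 1.88 and 3.81) and then further in the knockout (5.73, 6.18 and 6.79). The neural list had a median of 6.05 (SE 0.64) in the knockout against C3-DLL4 wild type, but more neural cells of the kind in untreated wild type are argued against, since the list had a median of -0.88 (SE 0.49) against untreated wild type and these RNAs rose by a median of 3.81 with C3-DLL4, where the list fell, while another kind of neural cell stays open. Against untreated wild type, a gain of the wider region is argued against, with a median of 0.19 (SE 0.11) over 66 genes within 5 Mb less that of all genes. These genes leave out the imprinted ones and the stretch next to MEG3, so a gain of the locus alone was not tested. A switch to the maternal imprint alone would lower the paternally expressed DLK1, RTL1 and DIO3, which were higher than in untreated wild type by a median of 3.74 (SE 0.28), DLK1 at 1640 ± 31 against 123 ± 1.6 CPM. A difference of the knockout clone apart from DLX3 was not tested and stays open.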
